A study of Mus musculus with 24 samples.

How the data were processed

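Gene expression was measured by RNA sequencing of whole liver from 24 mice with a loxP-flanked Slc25a47-Wars1 locus, 6 mice in each of 4 groups (Gfp, Cre+Gfp, Cre+Slc25a47 and Cre+Wars1). Per the labels, the mice were 18 weeks old and had fasted for 6 h, and the series description states that the viruses carried the hAAT promoter, which is active in hepatocytes. Sex and batches are not given in the sources used here. Per the labels' protocols, RNA was extracted in Trizol from frozen tissue and libraries were made with polyA enrichment for DNBSEQ sequencing. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a, and the builds GRCm38 and mm10 are named for the series. The deposited values are raw counts per gene as made by the authors, whole numbers with no normalization; the counter, the annotation release and the rule that left 17305 genes in the table are not given in the sources used here. Reads were not analysed here, so fragments of the transgenes were not separated from those of the endogenous genes.

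Total counts per library lay between 46775582 and 51656000, and the 20 most abundant genes held 23.1%, 21.2%, 20.7% and 23.8% of it on average in Gfp, Cre+Gfp, Cre+Slc25a47 and Cre+Wars1. Of the 17305 genes, on average 15029, 15625, 15584 and 14925 had at least 10 counts in a library of these groups. The median standard error of a log2 fold change was 0.107 in Cre+Slc25a47 against Cre+Gfp and 0.109 in Cre+Wars1 against Gfp, and the other comparisons lay between them. Every gene of the table had at least 72 counts over the 24 libraries. Of the gene IDs 17292 were matched to GENCODE M21 for position, and 16 symbols given to more than 1 gene were told apart by ID. Wars1 is listed as Wars. Libraries of a group were checked for duplicates: the chi-square per degree of freedom between pairs lay between 22.8 and 201, where copies would give about 1.

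Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr, which left 15975 genes, and library sizes were scaled with TMM factors. A quasi-likelihood model in edgeR with a mean per group was fitted to all 24 libraries, and 6 comparisons were tested with two-sided F tests. Benjamini-Hochberg adjusted p under 0.05 within a comparison counts as called, risen or fallen. Levels are CPM from edgeR on TMM-scaled library sizes. Slc25a47 and Wars1 were also compared by exact permutation of their CPM between groups of 6. Principal components were taken from log2 CPM with a prior count of 2. For a gene with 0 counts in a group, a fold is a bound against 3 counts over that group.

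Before the data were examined, 40 gene lists were written from general knowledge of mouse liver. They cover the neighbours of the locus, stress, mitochondrial, synthetase and ribosome genes, liver metabolism and zones, matrix, cell types and markers of sample quality. Members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. For each list the members called over all genes and adjusted over the list alone were counted. Genes were counted as moved back when called in Cre+Gfp against Gfp and called with the opposite sign in Cre+Wars1 or Cre+Slc25a47 against Cre+Gfp. Because these comparisons share the Cre+Gfp libraries, the count was set beside 20 simulations of unchanged groups and beside fits in which each comparison used 3 of the 6 Cre+Gfp libraries.

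The genes named in the text were chosen by a rule written before the data were examined. For Cre+Gfp against Gfp and for each transgene against Cre+Gfp these were the locus genes and their neighbours, then up to 8 risen and 8 fallen genes with the largest log2 fold change among those with adjusted p under 0.05, a mean of at least 2 CPM over all libraries and a symbol that is not a predicted model. Up to 4 members with the smallest p came from each list called by camera and up to 2 from lists about the study question that were not called. For the other 3 comparisons up to 5 risen and 5 fallen genes were taken, and a gene named in 1 comparison could be followed in the others. Acaca, Acadl, Asns, Atf4, Ddit3, Fgf21, Gdf15, Hspd1, Mab21l3, Me1, Pklr, Rian, Sds, Slc1a2, Sox9 and Tdo2, and in the closing section Alb, Cebpa, Gadd45a, Ghr, Igf1, Igfals, Socs2 and Cish, fall outside this rule and were chosen after their values were seen.

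The analysis was tested on simulated data with the depth and spread of the real libraries. The single genes to be changed were drawn only from genes above a minimum mean level, so recall for genes of lower level was not measured. Far fewer genes were changed than were called in most real comparisons, so recall there may differ. In Cre+Gfp against Gfp (15509 genes tested) edgeR called 80.6% of 67 genes changed 1.5-fold, 97.0% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 9 unchanged genes. In Cre+Slc25a47 against Cre+Gfp (15675 genes tested) it called 85.1% of 67, 98.5% of 67 and 100% of 66, and 11 unchanged genes. Recall at 1.5-fold was 71.6% in Cre+Wars1 against Cre+Gfp (15688 genes tested), 85.1% in Cre+Wars1 against Cre+Slc25a47 (15642), 76.1% in Cre+Wars1 against Gfp (15520) and 74.6% in Cre+Slc25a47 against Gfp (15521), each of 67 genes. Of 5 simulated lists with 20 genes raised 1.5-fold, 5 were called by each list test in each comparison. Genes were drawn independently in the simulations, so these do not show how the list tests behave when members of a list vary together. Of 200 genes simulated to change and move back with Wars1 only, 187 were counted as moved back with Wars1 and, by edgeR, 0 with Slc25a47.

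Alternatives planned before the data were examined were RLE size factors, DESeq2, limma voom with sample quality weights, no low-count filter, a filter of 10 counts in every library of a group, fits with only the 12 libraries compared, a replicate block, and the 20 most abundant genes left out of library sizes. After the data were seen, library totals without TMM factors, fits without Gfp replicates 5 and 6, and fits without the 6 libraries with over 10 CPM of pancreatic acinar genes were added. No library was left out of the values of the report except where this is stated. Groups were also regrouped at random, with 100 splits per comparison including the real one.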

Results

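Liver RNA sequencing covered 24 mice that carried a loxP-flanked Slc25a47-Wars1 locus on both alleles. Each of 4 groups held 6 mice, which received adeno-associated virus with a hepatocyte promoter: Gfp alone, Cre with Gfp (Cre+Gfp), Cre with Slc25a47 (Cre+Slc25a47) and Cre with Wars1 (Cre+Wars1). The mice were 18 weeks old and had fasted for 6 h. Counts were given for 17305 genes, and 15975 of these were tested. Total counts per library lay between 46775582 and 51656000. Levels are given below as CPM scaled with the TMM factors, which averaged 0.919, 1.11, 1.09 and 0.903 in Gfp, Cre+Gfp, Cre+Slc25a47 and Cre+Wars1.

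The recombined locus holds 2 genes on chromosome 12 of GRCm38. Slc25a47 (ENSMUSG00000048856, 108836046 to 108856815, plus strand) encodes a mitochondrial carrier of hepatocytes. Wars1 (ENSMUSG00000021266, 108860030 to 108894174, minus strand) is listed as Wars and encodes the cytosolic tryptophanyl-tRNA synthetase, which loads tryptophan onto its tRNA. Slc25a47 stood at 1013 ± 187 CPM (SD, n = 6) in Gfp and at 95.8 ± 22.6 CPM, 9.46% of that level, in Cre+Gfp. It reached 228 ± 37.6 CPM (22.5%) in Cre+Slc25a47 and 145 ± 17.0 CPM (14.3%) in Cre+Wars1. Wars stood at 22.4 CPM in Gfp, 12.1 ± 0.749 CPM (53.8%) in Cre+Gfp, 53.7% of the Gfp level in Cre+Slc25a47 and 436 ± 41.7 CPM (1948%) in Cre+Wars1. The exact permutation test (two-sided, 6 against 6) gave p = 0.00216 for both genes in Cre+Gfp against Gfp, the smallest value it can give. The same exact permutation test gave p = 0.00216 for Slc25a47 in Cre+Slc25a47 against Cre+Gfp and p = 0.00649 for Slc25a47 in Cre+Wars1 against Cre+Gfp. For Wars in Cre+Slc25a47 against Cre+Gfp the exact permutation p was 0.929. In every library the level of both genes lay on the side that its label calls for, although Slc25a47 stayed well under its Gfp level in Cre+Slc25a47. The counts do not separate transgene from endogenous transcripts.

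**Figure D1:**
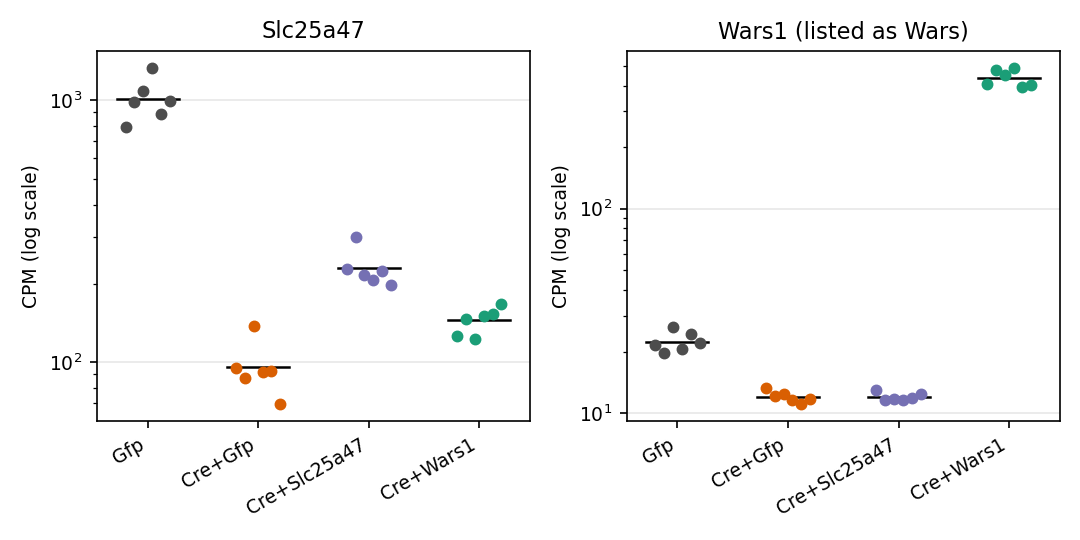
CPM (log scale) of Slc25a47 and Wars1 in the 6 libraries of each group, with group means as bars. Slc25a47 averaged 1013 CPM in Gfp and 95.8 CPM in Cre+Gfp, and Wars1 averaged 22.4 and 12.1 CPM.

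The 1st principal component held 58.4% of the variance and parted the libraries into a pair of clusters. Gfp (mean -47.3 ± 3.33, SD) lay beside Cre+Wars1 (-46.6 ± 2.45), and Cre+Gfp (47.6 ± 5.09) lay beside Cre+Slc25a47 (46.3 ± 3.59). The 2nd component held 6.3%. Total counts per library were divided along the same pairs of groups as the 1st component.

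**Figure D2:**
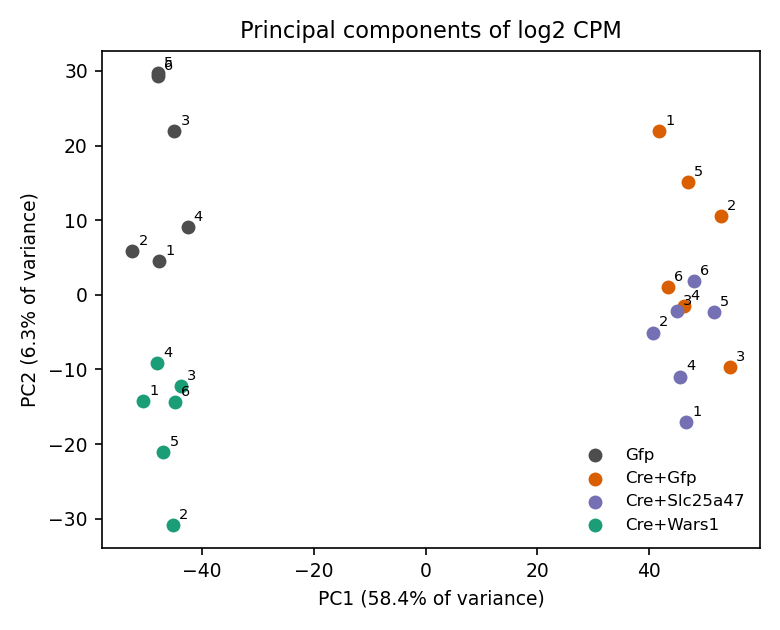
First and second principal component of log2 CPM for the 24 libraries, numbered by replicate. Cre+Gfp and Cre+Slc25a47 averaged 47.6 and 46.3 on the first, Gfp and Cre+Wars1 -47.3 and -46.6.

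Cre+Gfp against Gfp asks what Cre with loss of the locus does to the liver. Both came together, so they cannot be told apart. In Cre+Gfp genes of amino acid shortage and single mitochondrial stress genes such as Lonp1 and Hspa9 rose, as did nearly every ribosomal protein gene. The mRNA of most genes listed for tryptophan and NAD metabolism, the urea cycle and bile acid synthesis and transport fell, though not that of Tdo2. Most listed genes of matrix, monocyte-derived macrophages, T and NK cells and B cells rose, though not most of those of Kupffer cells or neutrophils. Genes that differ between male and female mouse liver shifted. With the edgeR quasi-likelihood test, 8979 of 15975 genes changed at an adjusted p under 0.05, 4739 risen and 4240 fallen, among them 921 risen and 999 fallen at least 2-fold. With library totals in place of TMM factors the median of all genes moved from 0.03 to 0.30 on the log2 scale, and 10998 genes changed, 80.6% of them risen in place of 52.8%. Small changes of broad gene groups are therefore given with both scalings where the sign differs.

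ATF4 drives the genes that cells switch on when amino acids run short or mitochondria fail. Of the 32 genes of the list integrated stress response (ATF4 targets), 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 fold change of 1.15. The camera test gave adjusted p = 4.3e-08 at its preset correlation and adjusted p = 0.142 with an estimated correlation. Atf5, a regulator of mitochondrial stress genes, rose by 2.02 ± 0.09 (SE) on the log2 scale, and 6 of 6 libraries lay above every Gfp library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.6e-14). Trib3 rose by 4.04 ± 0.27, Vldlr by 4.24 ± 0.25 and Psat1, an enzyme of serine synthesis, by 3.67 ± 0.24. Among genes singled out after their values were seen, the liver hormone Fgf21 went from 8.90 to 120 CPM, a log2 fold change of 3.75 ± 0.39. Asparagine synthetase Asns rose by 2.98 ± 0.36 (4.06 without Gfp replicates 5 and 6) and Ddit3 by 2.05 ± 0.23. Gdf15, another secreted stress signal of this list, showed no detectable change, at 0.14 ± 0.42 (adjusted p = 0.792 by the same test). Of the 21 genes of the endoplasmic reticulum unfolded protein response 8 fell and 13 were not called, with a median of -0.35 (camera adjusted p = 0.027, and adjusted p = 0.655 with an estimated correlation). Among them Xbp1 stood at -0.86 and Edem1 at -0.63, while with library totals 2 members rose and 2 fell. Cytosolic heat shock genes split, with 3 risen and 4 fallen of 12 and a median of 0.17 (camera adjusted p = 0.907).

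**Figure D3:**
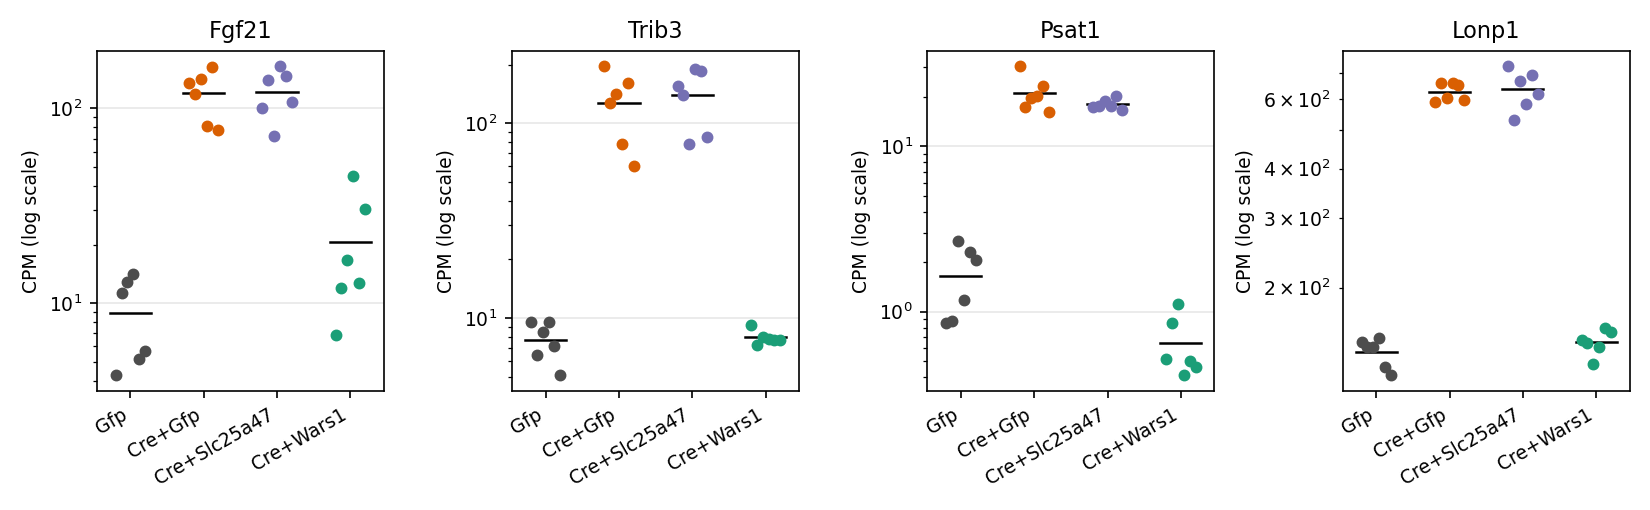
CPM (log scale) of Fgf21, Trib3, Psat1 and Lonp1 in the 6 libraries of each group, with group means as bars. Fgf21 averaged 8.90 CPM in Gfp, 120 in Cre+Gfp, 122 in Cre+Slc25a47 and 20.6 in Cre+Wars1.

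Within mitochondria the protein quality control genes changed unevenly. The protease Lonp1 rose by 2.19 ± 0.08 on the log2 scale (edgeR quasi-likelihood adjusted p = 6.7e-17) and the chaperone Hspa9 by 1.39 ± 0.06, each above every Gfp library in 6 of 6 libraries, while Hspd1 rose by 0.37 ± 0.08. Of the 18 mitochondrial chaperones and proteases, 9 rose and 2 fell, with a median of 0.14 (camera adjusted p = 0.0567). Nuclear-encoded respiratory chain genes fell slightly with TMM scaling, 24 fallen of 46 (23 fallen adjusted over the list alone), with a median of -0.17 (camera adjusted p = 1.7e-04, and adjusted p = 0.585 with an estimated correlation), but the median was 0.10 and 18 rose against 5 fallen with library totals. Mitochondrially encoded mRNAs had a median of -0.22, with 1 risen and 4 fallen of 13 (camera adjusted p = 0.129), and a median of 0.05 with library totals. The mitochondrial ribosome went both ways, with 17 risen and 11 fallen of 59 and a median of 0.04 (camera adjusted p = 0.748). The mitochondrial DNA maintenance and transcription list had 4 risen and 4 fallen of 19, a median of -0.00 (0.27 with library totals) and a camera direction of up (adjusted p = 0.907). Among aminoacyl-tRNA synthetases other than Wars1, the cytosolic Sars rose by 1.25 ± 0.10 and Gars by 0.85 ± 0.07, while Mars stood at -0.54. Of 19 cytosolic synthetases 8 rose and 2 fell, with a median of 0.06 (camera adjusted p = 0.216). Of 17 mitochondrial ones 7 rose and 3 fell (camera adjusted p = 0.748), and Wars2, which loads tryptophan in mitochondria, rose by 0.64 ± 0.08. The median of the mitochondrial synthetases was -0.03 and their mean 0.04, and with library totals 11 rose and the median was 0.23.

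Ribosomal protein genes rose together. Of 62 tested, 61 rose, with a median log2 fold change of 0.81 (camera adjusted p = 9.8e-26, and adjusted p = 0.320 with an estimated correlation). Rps26 rose by 1.03 ± 0.06, Rplp0 by 1.01 ± 0.07 and Rpl12 by 1.41 ± 0.09 (edgeR quasi-likelihood adjusted p = 9.1e-13, 7.3e-12 and 6.0e-12), each above every Gfp library in 6 of 6 libraries. With library totals 61 rose and the median was 1.08. Many ribosomal protein genes have processed pseudogenes, so single values are uncertain.

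Tryptophan leaves the liver through the kynurenine path, which also makes NAD, and several of its enzymes fell. Ido2 stood at -2.48, Qprt at -1.47, Kmo at -1.39 and Haao at -1.30 on the log2 scale, while the rate-limiting Tdo2, singled out after its value was seen, stayed at -0.04 ± 0.10 (edgeR quasi-likelihood adjusted p = 0.744). Of the 19 genes of tryptophan and NAD metabolism 13 fell and 1 rose, with a median of -0.65 (camera adjusted p = 9.3e-05, and adjusted p = 0.193 with an estimated correlation). The urea cycle lost Otc (-1.18 ± 0.09), Asl (-1.22 ± 0.10) and Arg1 (-0.96 ± 0.10), and 5 of its 7 genes fell (camera adjusted p = 0.00557, and adjusted p = 0.370 with an estimated correlation). Genes of periportal hepatocytes, the zone nearest the incoming blood, had 8 fallen and 2 risen of 12, led by Pigr (-2.86 ± 0.12) and Cyp2f2 (-1.86 ± 0.10) (camera adjusted p = 0.00101, and adjusted p = 0.320 with an estimated correlation). Pericentral genes had 6 fallen and 1 risen of 12, with Slc1a2 at -0.96 ± 0.10 (camera adjusted p = 0.0911). Bile acid synthesis and transport had 13 fallen and 2 risen of 20 (13 and 3 adjusted over the list alone), with Cyp8b1 at -2.24 ± 0.17 and Cyp27a1 at -0.86 ± 0.06 (camera adjusted p = 0.003, and adjusted p = 0.378 with an estimated correlation). Secreted plasma proteins and hepatocyte factors had 11 fallen and 2 risen of 14, among them Apoa1 (-1.53 ± 0.12) (camera adjusted p = 3.4e-04, and adjusted p = 0.142 with an estimated correlation).

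Lipid and sugar genes fell in part. Cholesterol synthesis (SREBP2 targets) had 15 fallen of 24, with Dhcr7 at -1.41 ± 0.18 and Insig1 at -1.11 ± 0.16 (camera adjusted p = 0.00101, and adjusted p = 0.573 with an estimated correlation), and 8 fallen against 1 risen with library totals. Fatty acid synthesis had 9 fallen and 4 risen of 17 (camera adjusted p = 0.129). Its regulator Srebf1 stood at -1.69 and Thrsp at -2.12, whereas Me1 rose by 0.95 ± 0.16. Gluconeogenesis had 6 fallen and 2 risen of 11, with Sds at -1.51 ± 0.17 and Fbp1 at 0.54 ± 0.07 (camera adjusted p = 0.0911). Fatty acid oxidation and ketogenesis (PPARalpha targets) went both ways, with 10 fallen and 7 risen of 27 (camera adjusted p = 0.482). Its median was -0.14 and its mean 0.00 with a camera direction of down, and the median turned to 0.13 with library totals.

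Genes of oxidative defence and proliferation rose. The bile acid exporter Abcc4 rose by 5.19 ± 0.26, the detoxifying enzyme Nqo1 by 1.82 ± 0.15 and Gstm3 by 3.07 ± 0.28, and 14 of 18 NRF2 targets rose while 2 fell (camera adjusted p = 2.5e-04, and adjusted p = 0.431 with an estimated correlation). Of 22 cell cycle genes 17 rose, with Mki67 at 1.30 ± 0.22 and Ccnb2 at 1.37 ± 0.26 (camera adjusted p = 0.00117, and adjusted p = 0.485 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 2.34 ± 0.32, and 8 of 16 p53 targets rose against 2 fallen (camera adjusted p = 0.128).

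Collagens and matrix genes, which mark scar formation, had 21 risen and 1 fallen of 24, with Col4a1 at 1.22 ± 0.11 and Col4a2 at 1.08 ± 0.10 against Fn1 at -0.93 ± 0.09 (camera adjusted p = 9.2e-05, and adjusted p = 0.457 with an estimated correlation). All 12 genes of hepatic stellate cells rose, Dcn by 0.60 ± 0.07 and Reln by 0.55 ± 0.06 (camera adjusted p = 1.7e-04, and adjusted p = 0.142 with an estimated correlation). Monocyte-derived macrophage genes had 9 risen of 12, with Itgax at 2.13 ± 0.17 (camera adjusted p = 0.00297, and adjusted p = 0.457 with an estimated correlation). T and NK cell genes had 11 risen and 1 fallen of 13, with Cd8a at 2.60 ± 0.48 and Ccl5 at 2.11 ± 0.33 (camera adjusted p = 0.00635, and adjusted p = 0.485 with an estimated correlation). B cell genes had 6 risen of 8 (camera adjusted p = 0.0949). Kupffer cell genes had 3 risen of 12 (2 adjusted over the list alone), Marco by 1.86 ± 0.30, and 11 risen without Gfp replicates 5 and 6 (camera adjusted p = 0.0836). Liver endothelial genes had 2 risen of 12, with a median of 0.02 (camera adjusted p = 0.748), and 11 risen with library totals. Cholangiocyte and ductular genes had 6 risen and 1 fallen of 10, with Krt23 at 3.82 ± 0.37 and Sox9 at -1.26 ± 0.22 (camera adjusted p = 0.0863). Of 5 red blood cell genes only the heme enzyme Alas2 passed, at -1.51 ± 0.08 (camera adjusted p = 0.0769).

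Immediate early genes split, with 5 risen and 3 fallen of 12, a median of -0.19 (0.08 with library totals), a mean of 0.25 and a camera direction of up (adjusted p = 0.907). Of the neutrophil genes (5 tested of 9) and adipocyte genes (4 tested of 7) edgeR called 0 and counted 0 at an unadjusted p under 0.05. DESeq2 called 0 of both and voom 0 and 1, with edgeR medians of -0.62 and -0.26 (camera adjusted p = 0.748 and 0.907), and the adipocyte median turned to 0.01 with library totals. Without Gfp replicates 5 and 6 the neutrophil median turned to 0.41 and edgeR called 1 gene as risen, so its sign rests on these libraries.

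Most listed acute phase and interferon response genes fell in these whole-liver counts, which do not separate cell types. Acute phase genes had 16 fallen and 2 risen of 19 (17 and 2 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 2.5e-04, and adjusted p = 0.516 with an estimated correlation). Lbp went from 217 to 33.4 CPM, and Hp stood at -2.81 on the log2 scale (-2.02 without Gfp replicates 5 and 6). Gfp replicates 5 and 6 held the highest acute phase levels, with Saa2 at 5116 and 7311 CPM against 51.3 to 389 CPM in the other Gfp libraries, and without these libraries 12 fell and 2 rose, with a median of -1.04. Interferon response genes had 16 fallen and 3 risen of 23 (17 and 3 adjusted over the list alone), with Ifit1 at -2.73 ± 0.23, Ifit3 at -1.66 ± 0.16 and Irf7 at -1.23 ± 0.15 (camera adjusted p = 1.0e-04, and adjusted p = 0.485 with an estimated correlation).

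**Figure D4:**
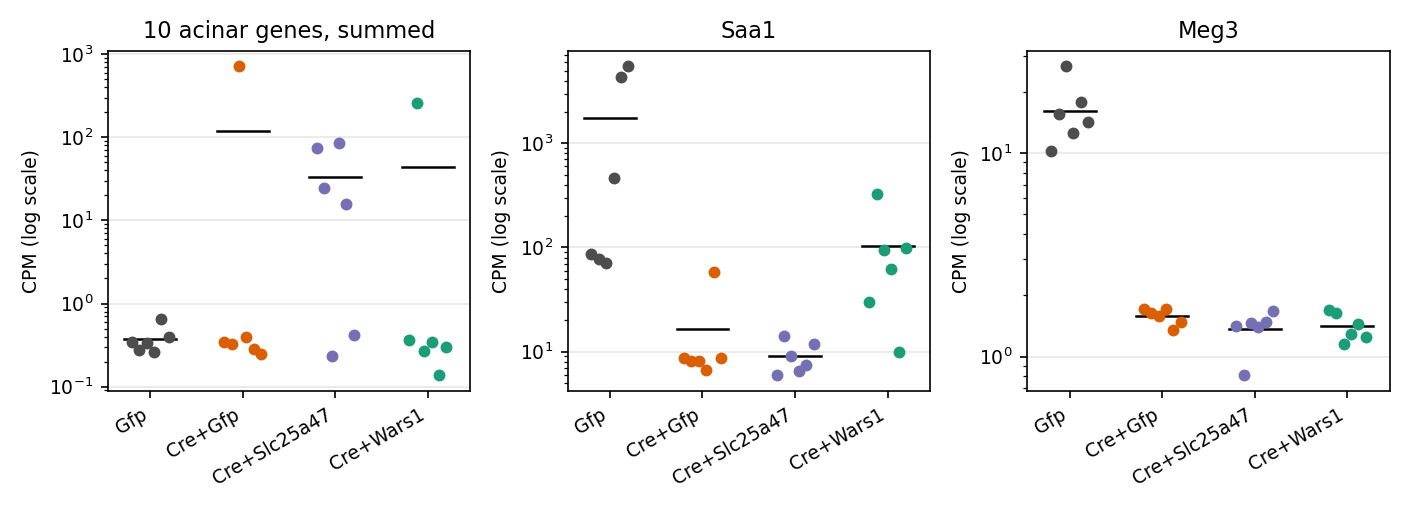
CPM (log scale) of 10 summed pancreatic acinar genes, of Saa1 and of Meg3 in the 6 libraries of each group, with group means as bars. The acinar sum reached 716 CPM in Cre+Gfp replicate 3, and Meg3 averaged 16.2 CPM in Gfp and between 1.37 and 1.58 CPM in the groups with Cre.

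Among the genes picked by size of change with counts in every group, the largest rise belonged to Vmn2r3, a vomeronasal receptor gene, which went from 0.0227 ± 0.0146 CPM (SD) in Gfp to 193 ± 89.2 CPM in Cre+Gfp, a log2 fold change of 12.91 ± 0.46. Enzymes that are typical of female mouse liver rose too: Cyp2a4 by 10.83 ± 0.64, Cyp2b9 by 9.05 ± 0.64 and Cyp3a44 by 7.48 ± 0.49. Tenm4 rose by 7.26 ± 0.34, Rap1gap2 by 5.62 ± 0.21 and Mab21l3 by 5.76 ± 0.35. Genes typical of male liver fell: the steroid enzyme Hsd3b5 stood at -5.87 (157 to 2.67 CPM), Selenbp2 at -5.37 and Mup11, a major urinary protein gene, at -4.87. Acpp stood at -5.23 and Capn8 at -5.08. Moxd1 fell by 4.78, although no Cre+Gfp library lay under every Gfp library, and stood at -2.14 without Gfp replicates 5 and 6. The serum amyloid genes Saa2 and Saa1 stood at -7.19 and -6.75, from Gfp means of 2162 and 1763 CPM that rest on replicates 5 and 6, and at -3.21 and -3.41 without these. Their Cre+Gfp means rest in large part on Cre+Gfp replicate 5, at 68.9 and 58.3 CPM (nearest 4.52 and 8.62). Members of the Cyp2a, Cyp2b, Cyp3a, Mup, Saa and Selenbp families share sequence with near copies, so their single values are uncertain. Of 10 pancreatic acinar cell genes 10 rose (camera adjusted p = 0.491), but Cre+Gfp replicate 3 held 716 CPM of them and the other Cre+Gfp libraries at most 0.396. Pnlip and Cpa1 had 0 counts in Gfp, and in Cre+Gfp they were at least 2007-fold and at least 1163-fold above the level that 3 counts over the Gfp group would give. Cel had 1 count in Gfp, a ratio of 4157 with a 95% counting interval from 746 to 164232. This interval is for counts pooled over each group and leaves out the spread between mice. The bounds and the ratio rest almost wholly on Cre+Gfp replicate 3. Without the 6 libraries with over 10 CPM of acinar genes, 1 acinar gene passed the filter, and it fell.

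Genes beside the locus went both ways. Of 6 tested neighbours 3 rose and 2 fell; the median was 0.10, the mean -0.47 and the camera direction down (adjusted p = 0.907). Evl rose by 0.80 ± 0.10, Slc25a29 by 0.41 ± 0.09 and Yy1 by 0.18 ± 0.07, while Degs2 stayed at 0.02 ± 0.34. Wdr25, whose start overlaps Wars on the other strand, fell by 0.88. The imprinted noncoding gene Meg3, 647 kb from the locus, fell by 3.35 from 16.2 ± 5.77 to 1.58 ± 0.139 CPM, with 6 of 6 Cre+Gfp libraries under every Gfp library.

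**Figure D5:**
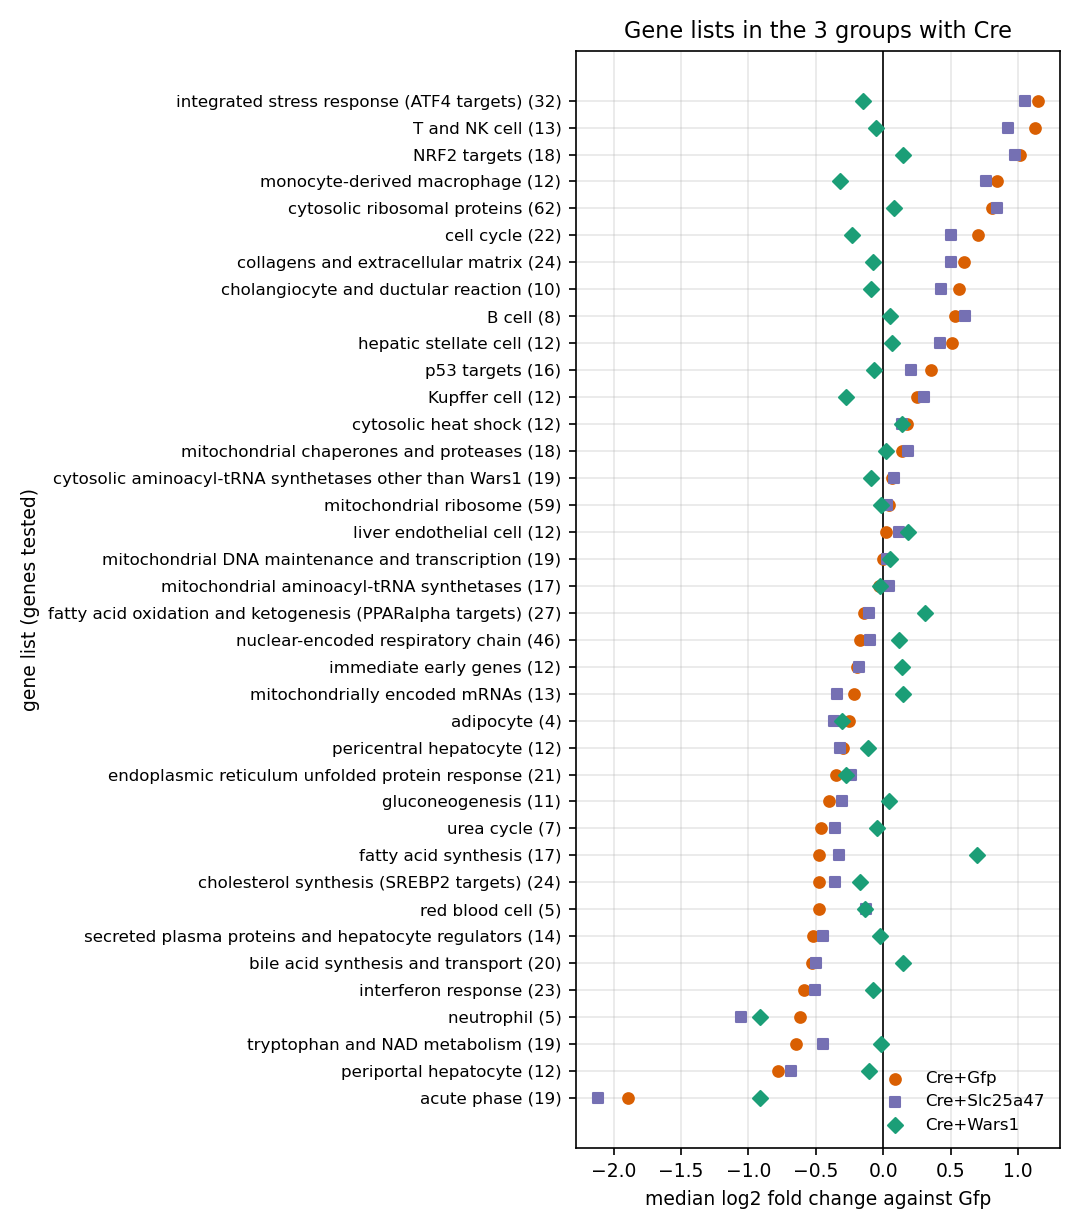
Median log2 fold change against Gfp of 38 gene lists (genes tested in parentheses) in the 3 groups with Cre. Cre+Gfp and Cre+Slc25a47 lie together and Cre+Wars1 lies nearer 0 in most lists, though not in fatty acid synthesis, while with library totals 7 medians in Cre+Gfp, 5 in Cre+Slc25a47 and 1 in Cre+Wars1 change sign, nuclear-encoded respiratory chain among them.

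Cre+Wars1 against Cre+Gfp asks what giving Wars1 back changes after recombination. Most ATF4 targets fell, and with TMM scaling most listed genes of tryptophan, bile acid and fatty acid metabolism rose. Most male-typical genes rose while most female-typical ones fell. In edgeR 8973 genes changed, 4118 risen and 4855 fallen, and with library totals 11316 changed, 17.6% of them risen in place of 45.9%, as the median of all genes moved from -0.04 to -0.33. Hsd3b5 rose by 6.14 ± 0.48, Mup9 by 5.08 ± 0.51, Acpp by 5.01 ± 0.35 and Mup19 by 4.98 ± 0.49, and Wars itself by 5.18 ± 0.08. Vmn2r3 stood at -11.66, Cyp2a4 at -8.34, Cyp2b9 at -7.96, Cyp3a44 at -7.93, Tenm4 at -6.72, Rap1gap2 at -5.89 and the cell death gene Hrk at -5.48. For each of these 12 genes 6 of 6 Cre+Wars1 libraries lay beyond every Cre+Gfp library. Slc25a47 rose by 0.59 ± 0.14 (edgeR quasi-likelihood adjusted p = 6.9e-04), but by 0.30 with library totals (adjusted p = 0.0525).

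Of the ATF4 targets 25 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -1.63 (camera adjusted p = 9.0e-10, and adjusted p = 0.140 with an estimated correlation). Psat1 stood at -5.03, Vldlr at -4.92 and Pycr1 at -3.23, and among the genes followed after their values were seen Asns stood at -5.23, Fgf21 at -2.54 and Atf4 at -0.61. Lonp1 stood at -2.10 and Hspa9 at -1.29, while the list of mitochondrial chaperones and proteases had 6 fallen and 3 risen (camera adjusted p = 0.148). Gars stood at -0.98 and Sars at -1.36 (10 fallen and 3 risen of the 19 cytosolic synthetases, camera adjusted p = 0.0406, and adjusted p = 0.589 with an estimated correlation). Of 62 ribosomal protein genes 61 fell, with a median of -0.72 (camera adjusted p = 5.7e-22, and adjusted p = 0.293 with an estimated correlation). Nuclear-encoded respiratory chain genes had 38 risen of 46 and a median of 0.32 (camera adjusted p = 5.4e-09, and adjusted p = 0.445 with an estimated correlation), against 11 risen and 11 fallen with library totals. Mitochondrially encoded mRNAs had 7 risen of 13 and a median of 0.25 (camera adjusted p = 0.0133, and adjusted p = 0.516 with an estimated correlation), which turned to -0.04 with library totals.

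Metabolic genes moved back toward or past their Gfp level. Fatty acid synthesis had 13 risen of 17 (14 adjusted over the list alone), Thrsp by 3.34 ± 0.24, Acacb by 2.19 ± 0.17, Srebf1 by 2.00 ± 0.15 and Fasn by 1.64 ± 0.21 (camera adjusted p = 3.3e-06, and adjusted p = 0.291 with an estimated correlation). Tryptophan and NAD metabolism had 14 risen and 1 fallen (15 and 2 adjusted over the list alone), Ido2 by 2.34 ± 0.15 and Kmo by 1.38 ± 0.08 (camera adjusted p = 5.4e-05, and adjusted p = 0.206 with an estimated correlation). Cyp8b1 rose by 2.67 ± 0.18, Otc by 1.32 ± 0.09 and Pigr by 2.65 ± 0.12. Bile acid synthesis and transport had 14 risen and 3 fallen of 20 (15 and 3 adjusted over the list alone) and the urea cycle 4 risen of 7 (camera adjusted p = 1.1e-04 and 0.0406, and adjusted p = 0.206 and 0.445 with an estimated correlation). With library totals tryptophan and NAD metabolism had 7 risen and 2 fallen, bile acid synthesis and transport 11 and 5, and the urea cycle 3 and 3. Collagens and matrix genes had 21 fallen and 1 risen, monocyte-derived macrophage genes 11 fallen of 12, T and NK cell genes 12 fallen and 1 risen of 13, and Kupffer cell genes 11 fallen of 12 (12 adjusted over the list alone). Their camera adjusted p values were 1.9e-05, 1.7e-04, 0.00383 and 0.00171, and with an estimated correlation the adjusted p values were 0.445, 0.291, 0.445 and 0.516. Cell cycle genes had 18 fallen and 1 risen, and interferon response genes 16 risen and 3 fallen (camera adjusted p = 5.2e-04 and 2.1e-04, and adjusted p = 0.445 and 0.516 with an estimated correlation).

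Both comparisons can be joined gene by gene. Of the 8979 genes changed in Cre+Gfp against Gfp, 7211 (80.3%) changed in the opposite direction in Cre+Wars1 against Cre+Gfp: 3837 rose and then fell, 3374 fell and then rose, and 26 changed again in the first direction. Independent lists of these sizes would share 2533 genes. Both comparisons share the Cre+Gfp libraries, and in 20 simulations of unchanged groups the count was 0, a value without real effects that does not measure what sharing adds to 7211. The covariance of the fold changes was -0.676 against -0.0212 in the simulations. With separate Cre+Gfp libraries for each comparison, 5704 of 7766 and 5432 of 7852 genes moved back. Genes risen in Cre+Gfp had a median log2 fold change against Gfp of 0.55 in Cre+Gfp and 0.02 in Cre+Wars1, and fallen genes -0.54 and -0.04. Meg3 did not move back, at -0.17 ± 0.19 in Cre+Wars1 against Cre+Gfp (edgeR quasi-likelihood adjusted p = 0.476), and with library totals it fell further, at -0.46.

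Cre+Slc25a47 against Cre+Gfp asks what giving Slc25a47 back changes after recombination. Slc25a47 itself rose by 1.25 ± 0.14 in 6 of 6 libraries, to 22.5% of its Gfp level, and was the only gene called by edgeR (quasi-likelihood adjusted p = 4.3e-05). For stress genes the log2 fold change was 0.03 ± 0.35 for Fgf21, -0.12 ± 0.32 for Asns and 0.11 ± 0.22 for Ddit3, and for Wars it was -0.00 ± 0.07. At an unadjusted p under 0.05 edgeR counted 1231 genes, DESeq2 called 12 genes (9 risen, 3 fallen) and limma voom 4 (3 risen, 1 fallen). Of the 8979 genes changed in Cre+Gfp against Gfp, 1 moved back, Slc25a47 itself. Of the lipogenic genes Srebf1 stood at 0.45 ± 0.14 and Thrsp at 0.70 ± 0.23 (adjusted p = 0.487 for both by the edgeR quasi-likelihood test). Of 5 red blood cell genes Alas2 stood at 0.39 ± 0.08 (adjusted p = 0.327 by the same edgeR test), and DESeq2 and voom each called 1 gene of this list as risen. Adjusted over the list alone, mitochondrially encoded mRNAs had 1 risen and 2 fallen of 13, with a median of -0.19 (camera adjusted p = 0.0174, and adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, fatty acid synthesis had 2 risen of 17, and its median was 0.25 (camera adjusted p = 9.2e-07, and adjusted p = 0.557 with an estimated correlation). Nuclear-encoded respiratory chain genes had a median of 0.07 with 0 of 46 called by edgeR, DESeq2 or voom and 12, 14 and 20 at an unadjusted p under 0.05 (camera adjusted p = 1.4e-07, and adjusted p = 0.559 with an estimated correlation). Tryptophan and NAD metabolism had a median of 0.12 with 0 of 19 called by edgeR, DESeq2 or voom and 6 risen in each at an unadjusted p under 0.05 (camera adjusted p = 1.3e-05, and adjusted p = 0.427 with an estimated correlation, fry adjusted p = 0.261). The list integrated stress response (ATF4 targets) had a median of -0.03 with 0 called by edgeR, DESeq2 or voom, and 0, 0 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.68).

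Cre+Wars1 against Cre+Slc25a47 tests the difference between both transgene groups directly. Wars reached 1948% of its Gfp level in Cre+Wars1 and Slc25a47 only 22.5% in Cre+Slc25a47. The kind of transgene and the level reached thus cannot be told apart. It resembled Cre+Wars1 against Cre+Gfp, with 8642 genes changed, 4116 risen and 4526 fallen, and 18.7% in place of 47.6% risen with library totals, as the median of all genes moved from -0.02 to -0.29. Hsd3b5 rose by 6.84 ± 0.50, Mup15 by 6.00 ± 0.63, Mup17 by 5.73 ± 0.64 and Mup9 by 5.25 ± 0.52. Vmn2r3 stood at -11.75, Cyp2a4 at -8.54, Cyp2b9 at -7.77 and Tenm4 at -6.92. ATF4 targets had 24 fallen and 1 risen (25 and 1 adjusted over the list alone), with a median of -1.55 (camera adjusted p = 2.6e-10, and adjusted p = 0.113 with an estimated correlation). Mitochondrially encoded mRNAs had 10 risen of 13 (11 adjusted over the list alone), with a median of 0.49 and, with library totals, 0.22 (camera adjusted p = 6.9e-04, and adjusted p = 0.460 with an estimated correlation). Slc25a47 was lower in Cre+Wars1, at -0.66 on the log2 scale, with 6 of 6 libraries under every Cre+Slc25a47 library.

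Cre+Wars1 against Gfp asks what differs from Gfp once Wars1 is given. Wars stood at 1948% of its Gfp level in Cre+Wars1 and Slc25a47 at 14.3%, and only Cre+Wars1 received Cre. Excess of Wars1, loss of Slc25a47 and Cre with recombination thus cannot be told apart here. Fat-making genes stood above Gfp, acute phase genes below, and most stress genes near it. In edgeR 1312 genes changed, 697 risen and 615 fallen, of which 66 and 138 changed at least 2-fold, and 520 risen and 721 fallen with library totals. Without Gfp replicates 5 and 6 the count was 475. All 17 fatty acid synthesis genes rose adjusted over the list alone and 15 over all genes (7 without these Gfp libraries), with a median of 0.70 (camera adjusted p = 6.1e-16, and adjusted p = 0.124 with an estimated correlation). Me1 rose by 1.32 ± 0.16, Pklr by 1.09 ± 0.16 and Acaca by 0.81 ± 0.12. Rgs16 rose by 2.39 ± 0.37 and Cyp2a5 by 2.19 ± 0.34, each above every Gfp library in 6 of 6 libraries, and Slc17a8 by 1.39 ± 0.27. Fatty acid oxidation had 12 risen of 27 (17 adjusted over the list alone, 1 over all genes without these Gfp libraries), with Acadl at 0.39 ± 0.07 and Ppara at 0.37 ± 0.08 (camera adjusted p = 4.2e-10, and adjusted p = 0.732 with an estimated correlation). Of 32 ATF4 targets 1 rose and 5 fell (6 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0366, and adjusted p = 0.767 with an estimated correlation). Asns lay under Gfp, at -2.25 ± 0.40 (-1.18 without Gfp replicates 5 and 6), as did Psat1, at -1.35 ± 0.28. Fgf21 stood at 1.21 ± 0.37 (edgeR quasi-likelihood adjusted p = 0.0426), but only 3 of 6 libraries lay above every Gfp library. It was not called by voom, with library totals, with the replicate block, with only the libraries of both groups, without the acinar libraries or without Gfp replicates 5 and 6. Acute phase genes had 11 fallen of 19 (15 adjusted over the list alone), with Lcn2 at -4.77 ± 0.89, Orm2 at -3.83 ± 0.80 and Saa3 at -4.09 ± 0.89 (camera adjusted p = 3.0e-07, and adjusted p = 0.767 with an estimated correlation). Without Gfp replicates 5 and 6 edgeR called 0 of the acute phase genes, 7 at an unadjusted p under 0.05, the median went from -0.91 to -0.29, Lcn2 and Orm2 stood at -1.13 and -0.42, and Saa3 turned to 0.19; with all libraries DESeq2 called 12 and voom 5. Meg3 stayed low, at -3.52 ± 0.19 (edgeR quasi-likelihood adjusted p = 4.8e-12), and Wars stood above Gfp by 4.28 ± 0.08. Of the genes changed in Cre+Gfp against Gfp, 616 (6.86%) were still called in the same direction and 273 in the opposite one, and 423 genes were called only here. Both comparisons share the Gfp libraries, so a deviation of these libraries can add to the 616.

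Cre+Slc25a47 against Gfp asks what stays different once Slc25a47 is given back. The picture was that of Cre+Gfp: 8855 genes changed, 4500 risen and 4355 fallen (78.5% in place of 50.8% risen with library totals, as the median of all genes moved from 0.02 to 0.26). Of the genes changed in Cre+Gfp against Gfp, 7724 (86.0%) were called in the same direction, and 1131 genes were called only here. The direct test of Cre+Slc25a47 against Cre+Gfp called 1 gene. The 1131 genes are therefore not shown to be particular to Cre+Slc25a47. Vmn2r3 rose by 13.01 ± 0.46 and Cyp2a4 by 11.03 ± 0.65, and Saa2 stood at -8.92 (-4.94 without Gfp replicates 5 and 6), Hsd3b5 at -6.57 and Capn8 at -5.51. ATF4 targets had 23 risen and 1 fallen, with a median of 1.05 (camera adjusted p = 3.9e-08, and adjusted p = 0.222 with an estimated correlation). Mitochondrially encoded mRNAs had 10 fallen of 13 and a median of -0.34 (camera adjusted p = 0.0268, and adjusted p = 0.579 with an estimated correlation), against 1 risen and 1 fallen with library totals. Slc25a47 stayed under Gfp, at -2.15 ± 0.14. Across the 3 groups with Cre, 597 genes differed from Gfp with the same sign, 267 risen and 330 fallen, Meg3 among them. The 3 comparisons share the Gfp libraries, so a deviation of these libraries would give the same sign in all 3.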

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

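The measures examined here, and both tests of the acinar transcripts, were chosen only after values had been seen. A single library was picked out where its gap to the nearest library, divided by the range of its group of 6, lay above Dixon's 95% critical value. Of 76 groups (19 measures in 4 groups) 14 held such a library; chance gives about 1 in 20 groups, here 3.8. Several measures follow each other, such as Saa1 and Saa2, so the groups are not independent.

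Transcripts of pancreatic acinar cells stood out in 3 groups. The summed level of 10 acinar genes was 716 CPM in Cre+Gfp replicate 3 (nearest library of the group 0.396), 259 CPM in Cre+Wars1 replicate 2 (nearest 0.362) and 0.642 CPM in Gfp replicate 5 (nearest 0.391). Single genes also stood out, in part in the same libraries. Slc25a47 stood at 138 CPM in Cre+Gfp replicate 3 (nearest 94.9) and at 302 CPM in Cre+Slc25a47 replicate 2 (nearest 227). Asns reached 106 CPM in Cre+Gfp replicate 1 (nearest 65.2), Cyp2a4 307 CPM in Cre+Gfp replicate 2 (nearest 139) and Hsd3b5 6.94 CPM in Cre+Gfp replicate 6 (nearest 2.90). Trib3 reached 9.25 CPM in Cre+Wars1 replicate 1 (nearest 7.95), and Meg3 was lowest in Cre+Slc25a47 replicate 2, at 0.810 CPM (nearest 1.39). The acute phase genes Saa1 and Saa2 stood at 58.3 and 68.9 CPM in Cre+Gfp replicate 5 (nearest 8.62 and 4.52) and at 325 and 353 CPM in Cre+Wars1 replicate 2 (nearest 97.9 and 78.5).

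Over 10 CPM of the acinar genes were found in 6 libraries: Cre+Gfp replicate 3, Cre+Wars1 replicate 2 and Cre+Slc25a47 replicates 1 (74.4 CPM), 2 (24.4), 4 (84.9) and 5 (15.9), while the Gfp libraries held 0.260 to 0.642 CPM. In the 5 others the log2 levels of the 10 genes had a Pearson correlation of at least 0.919 with those of Cre+Gfp replicate 3, a shared profile of the kind that pancreas tissue carried over with the liver would bring, so this remains a candidate explanation. A switch of acinar genes in hepatocytes in every recombined liver was argued against, since only 5 of the 12 libraries of Cre+Gfp and Cre+Slc25a47 passed 10 CPM. Whether tissue was taken along at dissection or material passed between tubes stays open.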

How the results depend on the processing

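Library totals without TMM factors and the fits without Gfp replicates 5 and 6 or without the 6 libraries with acinar transcripts were chosen only after values had been seen. Over the planned and added settings other than the fits with split Cre+Gfp libraries the number of genes changed lay between 8018 and 10998 in Cre+Gfp against Gfp and between 8164 and 11316 in Cre+Wars1 against Cre+Gfp, and 6490 to 9691 genes moved back with Wars1. The split fits gave 7766 and 7852 genes in Cre+Gfp against Gfp, and 5704 and 5432 moved back. Cre+Wars1 against Cre+Slc25a47 gave 5807 to 10818 genes and Cre+Slc25a47 against Gfp 6182 to 10490. In Cre+Slc25a47 against Cre+Gfp DESeq2 called 12 genes and limma voom 4 in place of 1, and 6 and 3 genes moved back with Slc25a47; the other settings gave 1 for both, and the cause was not tested. In Cre+Wars1 against Gfp the 1312 genes became 827 with only the libraries of both groups, 475 without Gfp replicates 5 and 6 and 748 without the libraries with acinar transcripts, each of which has fewer libraries in the fit. Saa3 in this comparison reversed, to 0.187 on the log2 scale without Gfp replicates 5 and 6, the libraries with the highest acute phase levels.

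For the single genes named in the text, DESeq2, RLE size factors, no filter, the stricter filter (where the gene was left in) and leaving out the 20 most abundant genes changed no call. Limma voom ended 8 calls, the replicate block 6, the fits with only the libraries compared 3, the fits without acinar libraries 1 and the fits without Gfp replicates 5 and 6 ended 9 beside the reversal, with Pnlip, Cpa1, Cel, Yy1, Fgf21, Lcn2, Orm2 and Saa3 among those ended by at least 1 setting. Library totals ended 2 calls (Slc25a47 in Cre+Wars1 against Cre+Gfp and Fgf21 in Cre+Wars1 against Gfp) and added 3 (Meg3 and Rian in Cre+Wars1 against Cre+Gfp and Socs2 in Cre+Gfp against Gfp). Of 240 list results the estimated correlation ended all 112 camera calls, and fry ended 29 and added 37. At the depth of these libraries, 46775582 to 51656000 counts, edgeR called 71.6% to 85.1% of simulated 1.5-fold changes in genes above a minimum mean level. Smaller changes thus go partly unseen, and recall for genes of lower level was not measured.

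The replicate numbers do not pair the libraries: the same-number correlations after removal of the group means had a median of 0.0131 (from -0.442 to 0.242), and 1 library lay closest to its own number. A replicate block gave 8868, 8905, 1, 8596, 1165 and 8773 genes in the 6 comparisons, 7157 genes moved back with Wars1 and 1 with Slc25a47.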

Other observations

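The lists of sex-biased genes, the genes named in this part and the tests described here were chosen, and the limit for reading the random regroupings was written down, only after results had been seen. Genes that differ between male and female mouse liver moved as groups. Of 21 male-predominant genes 19 fell and 1 rose in Cre+Gfp against Gfp, with a median log2 fold change of -2.05, and of 23 female-predominant genes 18 rose and 1 fell, with a median of 1.58. With Wars1 given back, 19 male-predominant genes rose and 1 fell against Cre+Gfp (median 2.34). Of the female-predominant ones 15 fell and 2 rose (median -1.66). Against Gfp, 2 male-predominant genes then stood higher, and 3 female-predominant genes stood higher and 1 lower. With Slc25a47 given back 19 male-predominant genes stood under Gfp and 1 above it (median -1.91). Of the female-predominant ones 16 stood above Gfp and 1 under it (median 1.68).

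Other liver genes traced the same division. The DNA damage gene Gadd45a rose by 2.17 ± 0.20 (SE) in Cre+Gfp against Gfp and stood at -1.74 in Cre+Wars1 against Cre+Gfp. The hepatocyte regulator Cebpa stood at -0.56 and then at 0.53, and albumin (Alb) at -0.61 and then at 0.74.

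Several explanations of the sex-biased shift were tested. Female animals were argued against by 4 Y-linked genes. Their summed level was at least 84.9% of the Gfp mean in each of the 12 libraries of Cre+Gfp and Cre+Slc25a47. An exchange among male animals would not show in these genes. A lower share of hepatocytes would lower genes of hepatocytes alike. As the only cause it was argued against by the rise of the female-predominant genes (median 1.58). That rise is part of the pattern itself, and whether a lower share adds to the fall of the male-predominant genes was not tested. For this fall, reads shared between paralogs were argued against by 10 male-predominant genes without close copies, whose median was -2.07. For the female-predominant genes shared reads were not tested. Lower growth hormone signalling in the hepatocytes is a hypothesis that may link the shift to Ghr (-1.39 ± 0.08), Igf1 (-0.72 ± 0.09) and Igfals (-1.05 ± 0.11). Only 3 of 5 genes of this path fell, as Socs2 (0.51 ± 0.31, and 0.78 and risen with library totals) and Cish (0.19 ± 0.57, and 1.21 without Gfp replicates 5 and 6) were not called by edgeR, so lower growth hormone signalling and other routes cannot be told apart without hormone levels, which were not analysed here.

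Meg3, Rian and Mirg, noncoding genes of an imprinted cluster on the chromosome of the locus, were low in all 18 libraries with Cre, with a summed level of 23.8 ± 8.57 CPM (SD) in Gfp and 2.49, 2.07 and 2.11 CPM in Cre+Gfp, Cre+Slc25a47 and Cre+Wars1. A few high Gfp libraries were argued against, since the lowest Gfp library stood 4.66-fold above the highest library with Cre. A part in the response that Wars1 moves back was argued against, since the median log2 fold change of Meg3 and Rian, the tested genes of the cluster, was -3.49 in Cre+Wars1 against Gfp. A change in cis around the recombined locus could not be decided: with Slc25a47, Wars, Wdr25 and the cluster itself left out, 1 of the 12 other tested genes within 1 Mb differed from Gfp with the same sign in all 3 groups with Cre, against 593 of 15958 elsewhere (Fisher exact p = 0.366). Cre itself and recombination were given together, so they cannot be told apart, and no control with Cre alone was held here.

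The libraries of each comparison were regrouped at random, 100 splits with the real one. In each comparison 87 to 92 of the 99 other splits called 0 genes. The values below give the real count and the highest of the other splits. The highest values of 4604, 5080, 4009, 4101 and 4086 came from splits that exchanged only 1 library of each group. Such splits keep most of the real contrast, so these values are not typical of random regrouping. For genes changed, 1 of 100 splits, the real one, reached the real count in Cre+Gfp against Gfp (8979 and 4604), Cre+Wars1 against Cre+Gfp (8973 and 5080), Cre+Wars1 against Cre+Slc25a47 (8642 and 4009), Cre+Wars1 against Gfp (1312 and 32) and Cre+Slc25a47 against Gfp (8855 and 4101), so chance was excluded there. In Cre+Slc25a47 against Cre+Gfp 10 of 100 splits called as many genes (1 and 603), so chance was not excluded for the count. The 1 gene called was Slc25a47, whose own exact permutation p was 0.00216. The split with 603 genes points to a structure of these libraries other than the transgene, which was not tested further. It set Cre+Slc25a47 replicates 1, 3, 4 and 6 and Cre+Gfp replicates 4 and 6 against the rest. Genes moved back gave 1 of 100 splits with Wars1 (7211 and 4086) and 10 of 100 with Slc25a47 (1 and 382), so chance was excluded for the count with Wars1 and not for the count with Slc25a47, which is Slc25a47 itself. For lists called by camera at its preset correlation, 18 of 100 splits reached the real count in Cre+Gfp against Gfp (18 and 26). In Cre+Wars1 against Cre+Gfp 7 did (21 and 24), and in Cre+Wars1 against Cre+Slc25a47 24 did (19 and 23). In Cre+Wars1 against Gfp 5 did (16 and 18), and in Cre+Slc25a47 against Gfp 6 did (21 and 25). Chance was thus not excluded for these counts. Splits that divide the groups unequally keep part of the real contrast, so the test cannot tell chance from a diluted real difference here. In Cre+Slc25a47 against Cre+Gfp 4 of 100 splits reached the real count of lists (17 and 19). This excludes chance at the level of 0.05 only for this test taken alone, as 1 of 6 such tests. In that comparison fry called 0 lists and no list passed with an estimated correlation.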
